A study of Mus musculus with 6 samples.

How the data were processed

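The authors sequenced total RNA from 3 wild type and 3 Tmem216-/- mouse samples at embryonic day 12 and deposited a table of TPM per gene. Per the submitters' processing notes, bases were called with CASAVA 1.8, reads were aligned to mm10 with HISAT2, transcripts were assembled with StringTie and levels were estimated with RSEM. The analysis starts from those TPM values; the number of reads per sample is unknown, and no count model was used. The table holds 56359 rows, of which 55536 carry an Ensembl identifier and 823 are assembled loci. Spreadsheet dates had replaced 27 gene names, and all 27 were recovered from the identifier. Where several identifiers share a symbol, the identifier with the highest mean over all samples kept the plain symbol. The table also has 2 further numeric columns that equal the group means to within 3.3e-06 and were left out.

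The choices below were written before the data were examined. Genes at 1 TPM or more in at least 3 of 6 samples were kept, which left 16411. Values were log2(TPM + 1). Tmem216-/- was compared with wild type by limma lmFit and eBayes with a trend, two-sided, and p values were adjusted over all tested genes by the method of Benjamini and Hochberg; a gene changed at an adjusted p under 0.05. SD is the sample standard deviation and SE the moderated standard error of the log2 fold change. Exact permutation p values are two-sided and take all splits of the 6 samples.

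Of 33 gene lists with 734 genes, written from general knowledge, 5 entries did not match the table. The 30 lists outside sex, mitochondrial and placental genes were tested by camera with a preset correlation of 0.01, and p values were adjusted over the lists. The same lists were tested by camera with the correlation estimated from the residuals and by fry. The fry p value asks whether the list moves in a single direction in these samples, and it uses rotations of the residuals in place of a comparison with other genes. Counts adjusted over the list alone apply the Benjamini and Hochberg method to the members of that list. Genes named in the text are Tmem216; Gli1, Ptch1, Hhip, Gli2, Gli3, Sufu and Smo; the 10 largest changes in each direction among genes that passed with groups that do not overlap, a mean of at least 1 TPM in the higher group and a symbol other than Gm followed by digits, a Rik clone name, an identifier or an immune receptor segment; and up to 4 members of each list with the smallest p (5 for Hedgehog targets). Some genes that this rule selects are not reported here. Other genes are said to have been chosen after their values were seen.

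The alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 5 TPM, median-of-ratios and quantile scaling, removal of haemoglobin, mitochondrial and ribosomal RNA genes, robust eBayes, eBayes without a trend, array weights, replicate number as a block, a Y-linked covariate for sex, each sample left out, and an absolute log2 fold change of at least 1. The fit of array weights did not converge fully and is reported as it came out. Covariates for liver and caudal Hox genes and removal of heart and muscle genes were added after the data were seen. The 3 further lists used in the closing tests (other heart muscle genes, other heart cells, tail bud) were written before their values were seen. Splits of the 6 samples into 3 against 3 were run through the same test.

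The scripts were tested on simulated data with 16411 genes, of which 200 were changed. Of 50 genes each, 52% were recovered at 2-fold, 88% at 4-fold, 92% at 8-fold and 96% at 16-fold, and 11 of 177 calls were false. A list shifted by 0.5 was called (adjusted p = 1.6e-11), and 0 of 29 other lists were called by camera. The simulated genes were drawn independently of each other, and the changed ones only from genes above about 5 TPM. In the real samples genes of a list can move together, and splits that mixed the genotypes called 5 to 16 lists. The simulation therefore does not show how often camera calls lists falsely in such data. Versions were Python 3.11.15, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.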

Results

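RNA sequencing measured gene levels in 6 samples of C57BL/6 mouse embryos at embryonic day 12, 3 wild type and 3 Tmem216-/-. The deposited values are TPM, so the number of reads behind a value is unknown. Of 55536 genes with an Ensembl identifier and 823 assembled loci, 30598 were above 0 in at least 1 sample. The 16411 genes at 1 TPM or more in at least 3 of the 6 samples were tested. The labels do not say which part of the embryo was taken, or whether the heart was included, so a fold change may reflect the tissue in a sample. They also do not say whether each sample is a separate embryo, so a p value measures the spread between these samples, which may be partly technical. Correlations of log2(TPM + 1) between samples ran from 0.934 to 0.975, and the lowest was between wild type replicates 2 and 3. Xist, expressed from the inactive X, was 0.07, 0.09 and 136 TPM in wild type and 219, 0.07 and 181 TPM in Tmem216-/-. Eif2s3y, a Y-linked translation factor, was 20.2, 46.4 and 0 TPM and 0.04, 32.5 and 0 TPM in the same order, so each sample showed the pattern of a single sex and each group held both sexes.

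Tmem216, which encodes a membrane protein of the ciliary transition zone, was 31.0, 30.7 and 17.4 TPM in wild type and 2.25, 0.51 and 1.39 TPM in Tmem216-/- (replicates 1, 2 and 3). It fell 19.1-fold, from 26.4 ± 7.74 to 1.38 ± 0.87 TPM (mean ± SD, n = 3 each; log2 fold change -3.55, SE 0.34, adjusted p = 0.0266). With each sample left out in turn the log2 fold change stayed between -3.81 and -3.25, and the adjusted p reached 0.189. The exact two-sided permutation p was 0.1, the smallest value that 3 against 3 samples can give. The gene (ENSMUSG00000024667, protein coding) lies on the minus strand of chromosome 19 at 10533865 to 10556238 in mm10, and the value covers the whole gene, so the remaining signal was not placed on exons. Cpsf7, which encodes a subunit of a 3' end processing complex, overlaps Tmem216 on the plus strand and had a log2 fold change of -0.06. Tmem138, which encodes another transition zone protein and lies beside Tmem216 (chromosome 19, 10570478 to 10577362), was 22.3 ± 2.88 and 23.5 ± 2.02 TPM, a log2 fold change of 0.08. The 21 tested genes within 500 kb had log2 fold changes from -0.28 to 0.58, and their lowest adjusted p was 0.746.

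Heart muscle genes rose in Tmem216-/-, and they make up nearly all of the difference that passed the test. Of 16411 genes, 17 changed at an adjusted p under 0.05: 16 rose, and Tmem216 was the only gene that fell. Myl7, the atrial myosin light chain, rose 96.7-fold from 2.95 ± 1.70 to 286 ± 143 TPM (log2 fold change 6.13, SE 0.43, adjusted p = 0.0174), and Myl2, the ventricular light chain, rose 81.2-fold from 4.44 ± 2.44 to 360 ± 197 TPM (6.00, adjusted p = 0.0198). Nppa and Nppb, which encode natriuretic peptides of heart muscle and lie side by side on chromosome 4, rose from 2.40 ± 2.28 to 181 ± 97.6 TPM (5.82, adjusted p = 0.0216) and from 0.23 ± 0.13 to 21.5 ± 8.25 TPM (4.13, adjusted p = 0.0174). Myl3, another ventricular light chain, rose from 2.32 ± 1.61 to 140 ± 75.8 TPM (5.38), and Mybpc3, the cardiac myosin binding protein, from 0.24 ± 0.14 to 24.1 ± 11.2 TPM (4.25). Myh6 and Myh7, the cardiac myosin heavy chains, rose from 4.29 ± 1.13 to 78.4 ± 24.5 TPM (3.88, adjusted p = 0.0174) and from 7.63 ± 1.34 to 134 ± 63.6 TPM (3.87, adjusted p = 0.0216). Ankrd1, a stretch-responsive nuclear protein of heart muscle, rose from 0.63 ± 0.40 to 25.8 ± 10.4 TPM (4.0), and Csrp3, a Z-disc LIM protein, from 2.52 ± 0.83 to 48.4 ± 23.9 TPM (3.72). A further 6 genes rose and are named after their values were seen: the thin filament genes Tnnt2 (3.19) and Tnni3 (3.31), the calcium pump regulator Pln (3.28), the small heat shock gene Hspb7 (3.60), the sarcomere ubiquitin ligase Trim55 (1.67) and the processed pseudogene Gm49739. Gm49739 was listed at 0 in all 3 wild type samples and at 16.1, 19.4 and 47.6 TPM in Tmem216-/-, and as a pseudogene it may share reads with its parent gene.

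All 18 measured genes of the cardiac muscle list were higher in each Tmem216-/- sample than in any wild type sample, with a median log2 fold change of 3.29 (camera adjusted p = 5.2e-52; adjusted p = 0.103 with an estimated correlation; fry adjusted p = 0.0179). Of these, 11 passed over all genes, and 18 passed when adjusted over the list alone. Tmem216-/- replicate 2 held the highest value of Myl7 (436 TPM, against 151 and 270 in replicates 1 and 3), Myl2 (568, against 177 and 335) and Nppa (294, against 131 and 120). In mm10, Myl7 lies on chromosome 11 at 5896637 to 5898782, Myl2 on chromosome 5 at 122100951 to 122113472, Nppa on chromosome 4 at 148000722 to 148002079 and Myh6 on chromosome 14 at 54941921 to 54966927. The counts depend on the samples used: leaving out wild type replicate 1 left 0 genes in limma, with 505 at an unadjusted p under 0.05, and without wild type replicate 3 or Tmem216-/- replicate 3 the 1 and 4 genes that passed were all lower, while the cardiac median stayed between 2.98 and 3.56 whichever sample was left out. Across all genes 732 had an unadjusted p under 0.05, against 821 expected by chance, and the groups of 1571 genes did not overlap (9.57%, against 10% by chance).

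**Figure D1:**
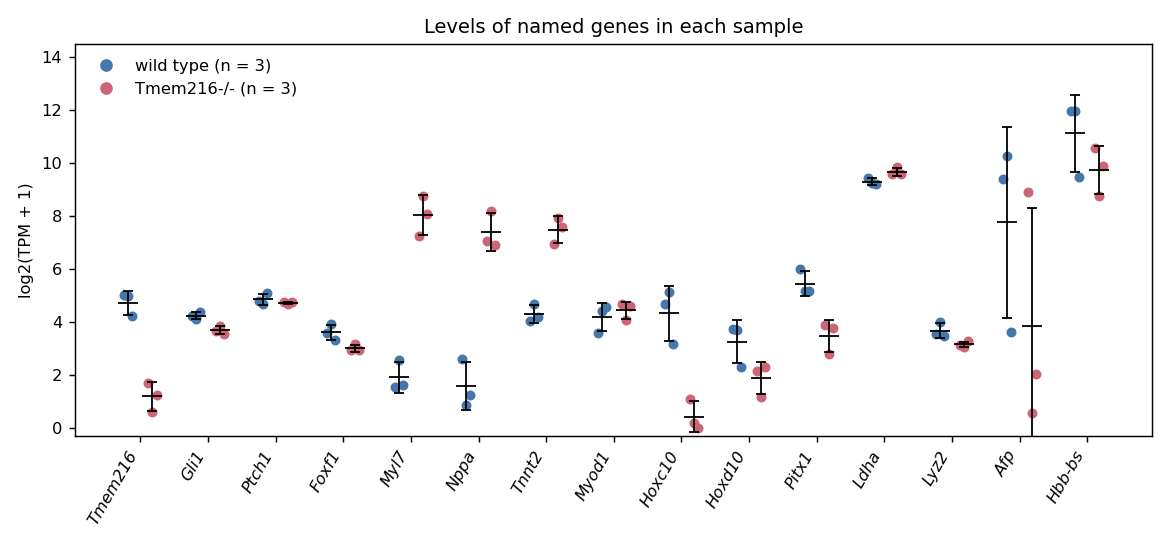
Log2(TPM + 1) of 15 genes, with each point a sample (3 wild type, 3 Tmem216-/-) and bars at the mean and SD. Tmem216 averaged 26.4 and 1.38 TPM, and Myl7 averaged 2.95 and 286 TPM, in wild type and Tmem216-/-.

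Hedgehog target genes shifted down by a small amount in Tmem216-/-, and no single target passed the test. The list of 15 measured targets fell with a median log2 fold change of -0.27 (camera adjusted p = 0.0154; adjusted p = 0.398 with an estimated correlation; fry adjusted p = 0.391). Of the 15, 12 were lower and 3 higher; 0 passed limma over all genes, 0 passed when adjusted over the list alone, and 2 had an unadjusted p under 0.05. Gli1, the transcription factor gene that is a direct readout of the pathway (chromosome 10, 127329882 to 127341974), was 17.8 ± 1.81 and 11.8 ± 1.35 TPM (log2 fold change -0.55, SE 0.14, adjusted p = 0.593). All 3 Tmem216-/- values of Gli1 lay below all 3 wild type values, with an exact two-sided permutation p of 0.1, the smallest possible. Foxf1, a mesenchymal forkhead target, was 11.4 ± 2.52 and 7.04 ± 0.78 TPM (-0.60, adjusted p = 0.884), and Hhip, a Hedgehog-binding antagonist, was 1.68 ± 0.12 and 1.11 ± 0.02 TPM (-0.35). In the other direction lay Osr1, a zinc finger gene of intermediate mesoderm (0.27), and Prdm6, a smooth muscle regulator (0.49). Ptch1, the Hedgehog receptor and a target (chromosome 13, 63508328 to 63573598), was 28.1 ± 4.41 and 25.5 ± 0.72 TPM (-0.13, adjusted p = 0.983).

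The genes of the Hedgehog pathway itself were close to wild type, with 12 of 24 measured components higher, 12 lower and a median log2 fold change of 0.00 (camera adjusted p = 0.871; without wild type replicate 3, median 0.08 and adjusted p = 0.0449). Gli2 and Gli3, the main activator and repressor transcription factors, had log2 fold changes of -0.10 (24.4 ± 5.29 and 22.4 ± 0.96 TPM) and 0.07 (26.4 ± 0.32 and 27.8 ± 0.61 TPM). Sufu, a Gli inhibitor, was at -0.10, and Smo, the signal transducer of the cilium, at -0.04 (89.8 ± 9.24 and 86.8 ± 2.11 TPM). Evc, a ciliary Smo partner, was at -0.22 and the kinase gene Ulk3 at -0.33, while the casein kinase gene Csnk1a1 was at 0.15 and the endocytic receptor gene Lrp2 at 0.29. With each sample left out the target list median ran from -0.33 to -0.11, and the call was lost without wild type replicate 3 (adjusted p = 0.241) and without Tmem216-/- replicate 1 (0.0716).

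Ventral neural tube genes fell slightly as a list, while the dorsal neural tube and forebrain lists did not pass, and all 3 results depended on single samples. In the ventral list 17 of 20 measured genes were lower, the median log2 fold change was -0.20 (camera adjusted p = 0.0154; adjusted p = 0.599 with an estimated correlation), and 0 passed limma over all genes or adjusted over the list alone, with 2 at an unadjusted p under 0.05. Without wild type replicate 3 the ventral median was -0.00059 (adjusted p = 0.897), without wild type replicate 2 it was -0.42 (adjusted p = 0.00477), and with a filter at 5 TPM the list did not pass either (adjusted p = 0.273). Lhx3 and Lhx4, LIM genes of motor neurons and V2 interneurons, were 4.09 ± 1.31 and 2.06 ± 0.48 TPM (-0.72) and 2.63 ± 0.90 and 1.28 ± 0.12 TPM (-0.64). Mnx1, a motor neuron gene, was at -0.59, and Sim1, a V3 interneuron gene, at 0.51. The dorsal neural tube list did not pass, with 17 of 26 higher, a median of 0.10 and a camera adjusted p of 0.392. It passed higher without wild type replicate 3 (median 0.31, adjusted p = 0.00793) and with array weights (0.31, 0.00530), and without wild type replicate 2 its direction turned (-0.08, adjusted p = 0.103). Within it Lhx2, a dorsal interneuron and forebrain gene, was at -0.47, Barhl2, a dorsal interneuron gene, at 0.46 and Pax7, a dorsal progenitor gene, at 0.37. Neural progenitor genes did not pass (median 0.10, camera adjusted p = 0.190). They passed higher without wild type replicate 3 (median 0.28, adjusted p = 9.2e-06) and with array weights (0.18, 0.0255), and without wild type replicate 2 their median was -0.10. The endothelin receptor gene Ednrb was at 0.32 and the Notch effector Hes1 at -0.31.

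The neuron list rose slightly, with 17 of 24 measured genes higher and a median log2 fold change of 0.07 (camera adjusted p = 0.00203; adjusted p = 0.487 with an estimated correlation). The call was lost without wild type replicate 2 (median -0.01, adjusted p = 0.560) and without Tmem216-/- replicate 2 (median 0.02, adjusted p = 0.107), and the median was 0.26 without wild type replicate 3. Map2, a dendrite microtubule gene, was 125 ± 9.69 and 155 ± 4.38 TPM (0.31, adjusted p = 0.760), Onecut1, a motor neuron and interneuron regulator, was at 0.59, Neurod1, a neurogenic factor, at 0.41 and Syt4, a vesicle gene, at 0.59. In limma 0 of the 24 passed over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05. The forebrain and eye list did not pass as a group: 13 of 20 were lower, the median was -0.38 and the camera adjusted p was 0.101. It passed lower without Tmem216-/- replicate 1 (median -0.49, adjusted p = 0.0157), with no filter (-0.26, 0.00846) and with the sex covariate (-0.44, 0.0309), while the median was -0.07 without wild type replicate 3 (adjusted p = 0.897) and -0.04 with a filter at 5 TPM (0.822). In limma 0 of the list passed over all genes, with 7 at an unadjusted p under 0.05, while Emx1, lower, and Cryab, higher, were among those that passed adjusted over the list alone. Emx1, a dorsal telencephalon gene, was 11 ± 1.49 and 2.38 ± 1.70 TPM (-1.93, adjusted p = 0.203 over all genes). Cryab, a lens and heart small heat shock gene, was 12.1 ± 3.34 and 35.9 ± 9.77 TPM (1.5, adjusted p = 0.203), and Nkx2-1, a ventral forebrain, lung and thyroid gene, was at -1.33.

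Hox genes fell as a list in Tmem216-/-, most strongly Hoxc10, Hoxc11 and Hoxc12. Of 36 measured Hox genes, 30 were lower and 6 higher, with a median log2 fold change of -0.46 (camera adjusted p = 3.2e-09; adjusted p = 0.217 with an estimated correlation). None of the 36 passed over all genes, and 3 passed lower when adjusted over the list alone. With each sample left out the list passed, with medians from -0.66 to -0.34. Hoxc10, a caudal and hindlimb gene (chromosome 15, 102966796 to 102971893), was 24.8, 34.4 and 7.96 TPM in wild type and 1.12, 0.13 and 0 TPM in Tmem216-/- (-3.91, adjusted p = 0.119). Hoxc11, its caudal neighbor, was 12.6, 4.34 and 5.43 TPM and 0, 0 and 0.18 TPM (-2.88, adjusted p = 0.0792), and Hoxc12 was 11, 3.90 and 6.81 TPM and 0.09, 0.07 and 0.48 TPM (-2.69, adjusted p = 0.0920). Hoxd1, an anterior Hox gene, was at -0.63. Hoxd13, a distal limb and genital gene named after its values were seen, was 32.4, 22.8 and 8.56 TPM and 10.3, 2.08 and 29.4 TPM.

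The limb patterning list fell, with 19 of 28 measured genes lower and a median log2 fold change of -0.23 (camera adjusted p = 0.00120; adjusted p = 0.462 with an estimated correlation). It shares Hoxd9 to Hoxd13, Hoxa11 and Hoxa13 with the Hox list, and each of these was lower. The fall of the limb list is therefore not independent of the Hox one. With array weights the list did not pass (median -0.17, adjusted p = 0.124), and with each sample left out the median ran from -0.40 to -0.15. Pitx1, the hindlimb identity gene (chromosome 13, 55825051 to 55836192), was 44.1 ± 15.9 and 10.8 ± 4.28 TPM (-1.96, adjusted p = 0.236) and was the only member that passed adjusted over the list alone, against 0 over all genes and 6 at an unadjusted p under 0.05 in limma. Hoxd10 was 9.45 ± 4.78 and 2.88 ± 1.43 TPM (-1.37), and Hoxa11, a zeugopod gene, was 12.4 ± 4.76 and 5.19 ± 2.93 TPM (-1.16). Wild type replicate 3 had 3.94 TPM of Hoxd10, level with the 3.95 TPM of Tmem216-/- replicate 3.

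**Figure D2:**
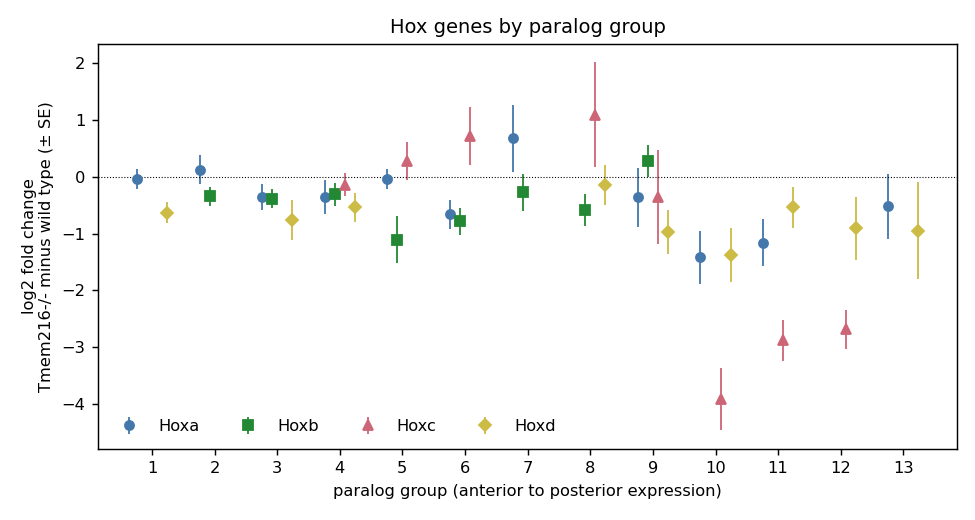
Log2 fold change of log2(TPM + 1), Tmem216-/- minus wild type, of 36 Hox genes by paralog group, with bars at the SE and symbols by cluster. Hoxc10 was at -3.91, Hoxc11 at -2.88 and Hoxc12 at -2.69.

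The skeletal muscle list rose in Tmem216-/-. Of 26 measured genes 21 were higher, with a median log2 fold change of 0.24 (camera adjusted p = 8.5e-08; adjusted p = 0.388 with an estimated correlation). The list passed whichever sample was left out, but the median ran from 0.07 without wild type replicate 1 to 0.50 without Tmem216-/- replicate 2, and was 0.08 with array weights. In limma 0 passed over all genes, 6 passed higher when adjusted over the list alone, and 6 had an unadjusted p under 0.05. Myl4, the embryonic and atrial light chain, was 42.3 ± 12.5 and 286 ± 99.6 TPM (2.71, adjusted p = 0.0530), and Actc1, cardiac alpha actin, was 144 ± 45.4 and 497 ± 110 TPM (1.82, adjusted p = 0.149). Tnni1, slow troponin I, was at 1.82 and Tnnc1, slow and cardiac troponin C, at 1.56 (64.7 ± 21.1 and 189 ± 40.4 TPM). These 4 genes are also active in the embryonic heart, so this rise may be part of the cardiac one and is not independent of it. Myod1, the skeletal muscle regulator named after its values were seen, was 18.1 ± 6.31 and 21 ± 4.55 TPM (0.25).

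Hypoxia and glycolysis genes rose by a modest amount, with 22 of 26 measured genes higher and a median log2 fold change of 0.23 (camera adjusted p = 8.5e-08; adjusted p = 0.0938 with an estimated correlation; fry adjusted p = 0.0442). With each sample left out the list passed camera, with medians from 0.21 to 0.26. In 11 of the 26 each Tmem216-/- sample lay above each wild type sample, against 5% by chance for that direction; in limma 0 passed over all genes, 1 passed adjusted over the list alone and 11 had an unadjusted p under 0.05. Adm, which encodes a hypoxia-induced vascular peptide, was 1.52 ± 0.56 and 4.32 ± 0.68 TPM (1.09, adjusted p = 0.315) and was the member that passed over the list alone. Kdm3a, a hypoxia-induced histone demethylase gene, was 46.7 ± 5.13 and 61.2 ± 1.95 TPM (0.39), and the glycolytic genes Aldoa and Ldha were 396 ± 37.4 and 509 ± 29.8 TPM (0.36) and 633 ± 54.8 and 816 ± 85.4 TPM (0.36).

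The immediate early and stress list rose, with 17 of 24 measured genes higher and a median log2 fold change of 0.16 (camera adjusted p = 0.0116; adjusted p = 0.473 with an estimated correlation). The call was lost without wild type replicate 2 (adjusted p = 0.147), without wild type replicate 3 (0.152), without Tmem216-/- replicate 2 (median -0.01, adjusted p = 0.399), with no filter (0.0572) and with array weights (0.0582). Hspb1, a small heat shock gene, was 36.9 ± 6.76 and 66.0 ± 6.30 TPM (0.83, adjusted p = 0.207) and was the only member that passed adjusted over the list alone, against 0 over all genes in limma with 3 at an unadjusted p under 0.05. Atf3, a stress transcription factor, was at 0.84 and Ier3, an early response gene, at 0.72. The endothelium list also rose, with 15 of 18 higher and a median of 0.12 (camera adjusted p = 0.000528; adjusted p = 0.363 with an estimated correlation). With each sample left out it passed, with medians from 0.04 to 0.20, but the call was lost with the hepatocyte and posterior Hox covariates. Tek, an angiopoietin receptor, was 6.58 ± 0.51 and 10.3 ± 0.75 TPM (0.58), and Gja5, a connexin of arteries and atria, was 8.94 ± 1.65 and 15.1 ± 1.47 TPM (0.70); these 2 passed adjusted over the list alone, against 0 over all genes in limma and 2 at an unadjusted p under 0.05. Pecam1, an endothelial adhesion gene, was at 0.23 and the VEGF receptor gene Flt1 at 0.34.

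Liver genes fell as a list, but their levels followed single samples more than genotype. All 22 measured hepatocyte genes were lower, with a median log2 fold change of -1.61 (camera adjusted p = 8.5e-08; adjusted p = 0.462 with an estimated correlation), while in limma 0 passed over all genes or adjusted over the list alone and 1 had an unadjusted p under 0.05. The median ran from -0.95 without wild type replicate 1 to -2.87 without wild type replicate 3, and the list passed whichever sample was left out. Afp, the fetal serum protein gene named after its values were seen, was 669, 1228 and 11.3 TPM in wild type and 480, 0.47 and 3.07 TPM in Tmem216-/-. Vtn, which encodes vitronectin, was 43.0 ± 7.33 and 31.0 ± 3.19 TPM (-0.45), Ttr, a thyroxine carrier of liver and choroid plexus, was at -0.75, and the apolipoprotein gene Apoc1 was at -1.46 with an SE of 0.75.

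The macrophage and leukocyte list fell, with 13 of 15 measured genes lower and a median log2 fold change of -0.27 (camera adjusted p = 0.000107; adjusted p = 0.207 with an estimated correlation). In limma 0 passed over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05. With each sample left out the list passed, with medians from -0.34 to -0.24. The call was lost with the hepatocyte and posterior Hox covariates, which were added after the data were seen. Lyz2, the myeloid lysozyme gene, was 11.9 ± 2.70 and 7.89 ± 0.68 TPM (-0.52), Fcer1g, an Fc receptor chain gene, was at -0.38, C1qc, a complement gene of macrophages, at -0.34 and Prtn3, a granule protease gene, at -0.33. The erythroid list did not pass, with 20 of 25 lower, a median of -0.25 and a camera adjusted p of 0.161. It passed lower without wild type replicate 3 (median -0.57, adjusted p = 6.6e-06), without Tmem216-/- replicate 1 (-0.48, 0.00171), with quantile scaling (-0.26, 0.0455) and with haemoglobin, mitochondrial and ribosomal RNA genes left out (-0.28, 0.0161). Its direction turned without wild type replicate 2 (median 0.02, adjusted p = 0.801) and without Tmem216-/- replicate 2 (0.00, 0.116). The embryonic globin genes Hbb-bh1 and Hba-x were at 0.64 and 0.48, and the adult globin gene Hbb-bs was at -1.40 with an SE of 0.77; the globin genes share sequence, so their separate levels are uncertain.

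Endoderm and epidermis lists fell. Of 15 gut and lung endoderm genes 10 were lower, with a median log2 fold change of -0.35 (camera adjusted p = 0.0108; adjusted p = 0.342 with an estimated correlation). The call was lost without wild type replicate 1 (median -0.18, adjusted p = 0.116), wild type replicate 2 (0.0510) or Tmem216-/- replicate 1 (0.0522), and with array weights (0.124), the sex covariate (0.0568) and a filter at 5 TPM (0.0729). The tight junction genes Cldn6 and Cldn7 were 15.3 ± 3.64 and 9.08 ± 0.85 TPM (-0.67) and 6.26 ± 1.33 and 3.44 ± 1.18 TPM (-0.73). Bmp4, a signal gene of mesenchyme and gut, went the other way at 23.7 ± 3.42 and 38.7 ± 3.81 TPM (0.69, adjusted p = 0.310) and was the only member that passed adjusted over the list alone, against 0 over all genes in limma with 5 at an unadjusted p under 0.05. Of 17 epidermis genes 15 were lower, with a median of -0.25 (camera adjusted p = 0.00120; adjusted p = 0.473 with an estimated correlation), and in limma 0 passed over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05. With array weights the epidermis list did not pass (median -0.12, adjusted p = 0.321), and with each sample left out its median ran from -0.39 to -0.17. Tfap2c, a surface ectoderm regulator, was at -0.80, the basal keratin genes Krt14 and Krt5 were at -0.63 and -0.56, and Dsp, a desmosome gene also used in heart, was at 0.53.

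Cell cycle genes fell very slightly, with 25 of 32 measured genes lower and a median log2 fold change of -0.06 (camera adjusted p = 0.0104; adjusted p = 0.342 with an estimated correlation). The call was lost without wild type replicate 1 (adjusted p = 0.0658), without wild type replicate 2 (0.410) and with the sex covariate (0.0898), and the medians with each sample left out ran from -0.10 to -0.05. Mcm5, a replication helicase gene, was 149 ± 8.08 and 122 ± 5.81 TPM (-0.28), Cdc6, a licensing gene, was at -0.32, the mitotic kinase gene Aurka at -0.20 and the replication gene Cdc45 at -0.17. In limma 0 of them passed over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05.

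Lists of genes that build cilia did not pass, and with a sample left out their medians ran from -0.03 to 0.08 (transition zone), 0.02 to 0.08 (intraflagellar transport) and -0.26 to 0.06 (motile cilia). The transition zone, Joubert and Meckel list did not pass, with 17 of 26 measured genes higher, a median log2 fold change of 0.04 and a camera adjusted p of 0.399. Cspp1, a centrosome and cilium gene, was 36.9 ± 8.11 and 44.7 ± 4.03 TPM (0.29, adjusted p = 0.983), and Tmem80, a transition zone gene, was at -0.19. Intraflagellar transport and BBSome genes did not pass either, with 23 of 32 higher, a median of 0.07 and a camera adjusted p of 0.0723 (0.0255 with array weights); Bbs2, a BBSome gene, was at 0.24 and Wdr35, a retrograde transport gene, at 0.16. Of 12 measured motile cilia genes 8 were lower (median -0.11, camera adjusted p = 0.225). Ccno, a multiciliogenesis cyclin gene, was 2.37 ± 0.37 and 0.75 ± 0.13 TPM (-0.94, adjusted p = 0.278) and passed adjusted over that list alone, while Rfx2 and Foxj1, motile cilia regulators, were both at -0.37.

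The remaining lists did not pass, and with a sample left out their medians moved across 0 for Wnt targets (-0.19 to 0.05), planar cell polarity (-0.12 to 0.07), neural crest (-0.16 to 0.01) and p53 genes (-0.06 to 0.03), but not for cartilage (-0.22 to -0.06) or kidney (-0.19 to -0.06). Canonical Wnt targets had a median log2 fold change of -0.04 (camera adjusted p = 0.428), with the transcription factor gene Tcf7 at -0.20 and the feedback gene Notum at -0.25. Planar cell polarity genes had a median of -0.00 and a mean of 0.01, so the signs differed (camera adjusted p = 0.871; without wild type replicate 3, median 0.07 and adjusted p = 0.0395), with the receptor gene Fzd3 at 0.35 and the polarity scaffold gene Scrib at -0.14. Cartilage genes had a median of -0.13 (camera adjusted p = 0.182), with the matrix genes Epyc at 0.51 and Matn1 at -0.51. Kidney genes had a median of -0.14 (camera adjusted p = 0.101); Pax8, a nephron gene, was 11.6 ± 1.49 and 5.80 ± 1.43 TPM (-0.90, adjusted p = 0.382) and passed adjusted over that list alone. Neural crest and glia genes had a median of -0.12 (camera adjusted p = 0.809), with the melanocyte regulator Mitf at 0.52 and the receptor gene Kit at -0.26. Genes of the p53 response had a median of -0.02 and a mean of 0.01 (camera adjusted p = 0.978), with the stress gene Sesn2 at -0.29 and the cyclin gene Ccng1 at 0.49. Extracellular matrix genes had a median of 0.10 (camera adjusted p = 0.0747), and passed higher without wild type replicate 3 (adjusted p = 0.0165), Tmem216-/- replicate 2 (0.0233) or Tmem216-/- replicate 3 (0.0240) and with quantile scaling (0.0455), with medians from 0.02 to 0.11 as samples were left out. Eln, which encodes elastin, was 15.0 ± 2.90 and 24.8 ± 2.86 TPM (0.70, adjusted p = 0.593), and Fn1, which encodes fibronectin, was at 0.17. The placenta and yolk sac list had 3 measured genes and was not tested (median 0.03). The 14 mitochondrially encoded genes, used only as a measure of sample quality, had a median of 0.31, and their separate levels are uncertain because nuclear copies share their sequence. The 5 sex-linked genes had a median of -1.31, which follows the sexes of the samples.

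**Figure D3:**
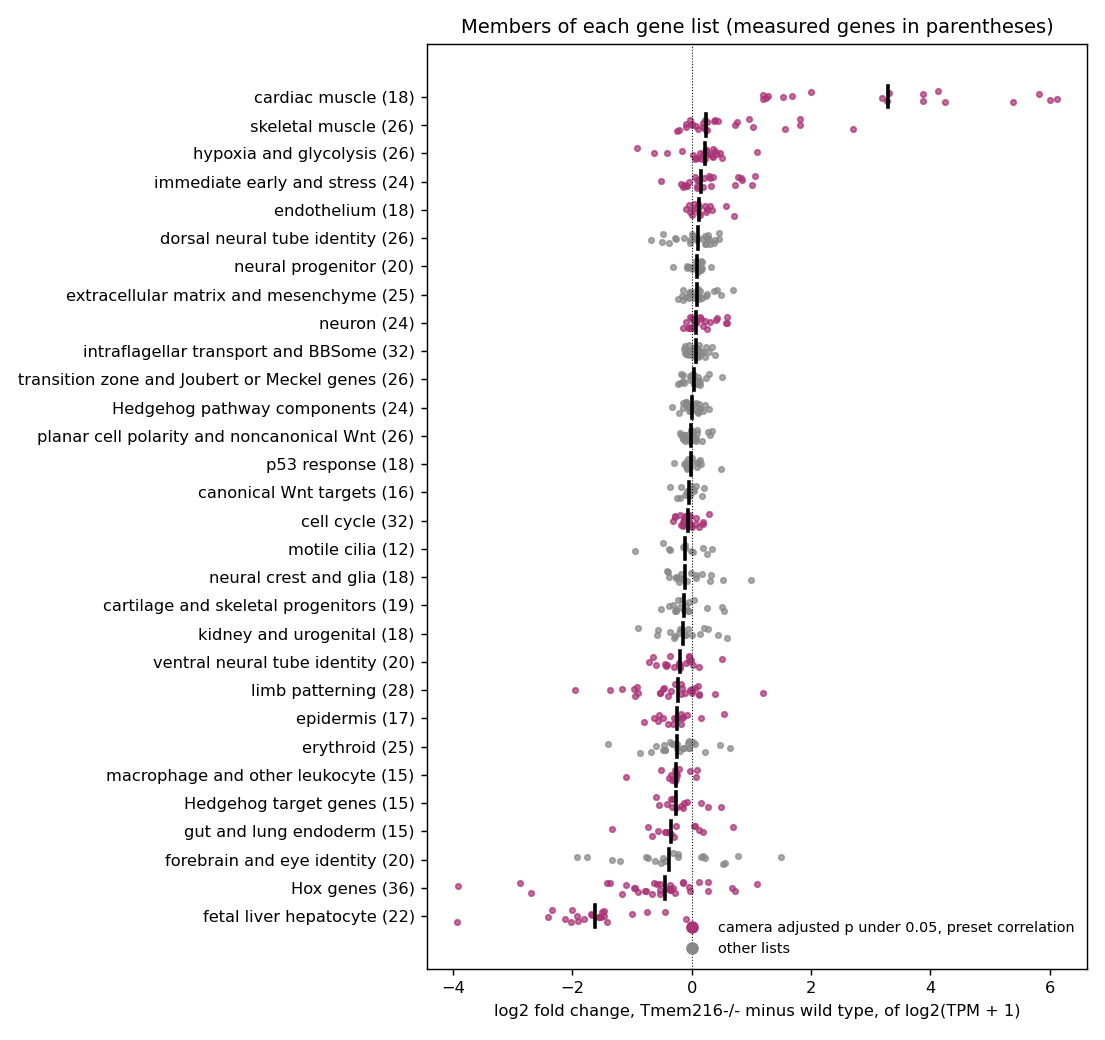
Log2 fold change of log2(TPM + 1), Tmem216-/- minus wild type, with each point a gene of 1 of the 30 tested lists and each bar the median; colored lists passed camera at the preset correlation. The cardiac muscle list was at 3.29, the Hox list at -0.46 and the Hedgehog target list at -0.27.

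Across the 30 lists tested, 15 passed camera at the preset correlation of 0.01, 6 higher and 9 lower. With an estimated correlation camera called 0 lists, the lowest adjusted p was 0.0938 and 4 lists had an unadjusted p under 0.05, while fry called 2, cardiac muscle and hypoxia. With a sample left out fry called 0 lists in 5 of 6 cases (cardiac adjusted p = 0.139 without wild type replicate 1), and hypoxia did not pass fry with median-of-ratios scaling (adjusted p = 0.135). Fold changes on log2(TPM + 1) understate the difference for genes with low values.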

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

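Tmem216 was lower under every alternative, but its limma adjusted p rose above 0.05 in several: pseudocount 0.1 (-4.31, adjusted p = 0.0667), no filter (-3.55, 0.0874), array weights (-3.53, 0.280), sex covariate (-3.56, 0.0810), and, as alternatives chosen after seeing the data, hepatocyte covariate (-3.11, 0.0847), heart genes left out (-3.55, 0.0750) and posterior Hox covariate (-2.45, 0.931). The posterior Hox covariate itself differs between the genotypes, so it takes up part of any genotype difference. Leaving out single samples gave -3.81 to -3.25, with adjusted p up to 0.189; fewer samples give less power. Genes changed fell from 17 to 0 with no filter (1207 at an unadjusted p under 0.05 in limma), array weights (531), the hepatocyte covariate (979), heart genes left out (692) and the posterior Hox covariate (339), and ran from 0 to 20 with single samples left out. Leaving out heart genes removes 11 of the 17 genes from the test, so most of that fall is built in. The log2 fold change and SE (0.34) of Tmem216 did not move with it. Genes higher were 16, against 10 with pseudocount 5, 0 in the same 5 settings and 0 to 16 with samples left out. Genes lower were 1, against 2 with either pseudocount, 4 without a trend, 0 in the same 5 settings and 0 to 8 with samples left out. The share higher was 94.1%, 83.3% with pseudocount 5, 82.6% without a trend, 60% without Tmem216-/- replicate 1 and without its replicate 2, and 0% without Tmem216-/- replicate 3 (4 genes) and without wild type replicate 3 (1 gene).

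Lists changed were 15, against 9 with the hepatocyte covariate, 8 with the posterior Hox covariate (4 of the 15 calls kept), 17 with quantile scaling, 0 with an estimated correlation (4 at an unadjusted p under 0.05), 2 with fry and 11 to 18 with samples left out. The 7 calls lost with the hepatocyte covariate were neuron, endothelium, leukocyte, hepatocyte, endoderm, stress and cell cycle. That covariate is the mean of the hepatocyte list, so the loss of the hepatocyte call was largely built in. With the posterior Hox covariate the ventral neural tube, skeletal muscle, cardiac and hypoxia lists kept their calls, and the limb list passed in the other direction (median 0.18, adjusted p = 0.0408). The limb list shares Hox genes with that covariate, so its turn is partly built in. The 2 lists of fry were 1 with a filter at 5 TPM, with median-of-ratios scaling, with the sex covariate, with haemoglobin genes left out and without Tmem216-/- replicate 1, 3 with quantile scaling, and 0 with array weights, each of the 3 added alternatives and each other sample left out. With heart and muscle genes left out the cardiac and skeletal muscle lists were not tested. Without wild type replicate 3, 12 of the 15 calls were kept and 6 other lists passed. The Hedgehog target median was -0.27, against -0.11 with array weights (adjusted p = 0.124), -0.30 with the posterior Hox covariate (0.0700), -0.27 with an estimated correlation (0.398) and with fry (0.391), and -0.33 to -0.11 with samples left out (adjusted p = 0.241 without wild type replicate 3 and 0.0716 without Tmem216-/- replicate 1).

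Of 129 named genes 92 kept the same sign and the same side of the threshold under every alternative. None of those 92 passed in the main test, so for them the same result means not passing again. Each named gene that passed lost its call in some alternatives, from 6 for Nppb to 12 for Tmem216. Nppb was tested in 17 alternatives, against 20 for Myl7 and 21 for Tmem216, so these counts do not rank the genes. Of the 129, 20 reversed at least once. Without wild type replicate 3, Gli2 was 0.0640, Sufu 0.0838, Smo 0.0286, Scrib 0.0126 and Dchs1 0.0321 (lowest with samples left out -0.222, -0.247, -0.119, -0.250 and -0.347). With the hepatocyte covariate the Btg2 log2 fold change was -0.0418. With the posterior Hox covariate these genes reversed: Osr1 -0.0447, Hoxd10 0.428, Hoxa11 0.514, Bbs2 -0.0109, Notum 0.0538, Hbb-bs 1.22, Nfe2 0.628, Apoc1 0.401, Ahsg 0.752, Krt14 0.0690, Krt5 0.0186, Cited1 -0.292, Btg2 -0.198, Atf3 -0.0125 and Fbn1 -0.0209. Hoxd10 and Hoxa11 are part of the mean that makes up this covariate, so their reversal is partly built in. For the other genes the cause was not tested.

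With replicate number as a replicate block 25 genes changed, 84% of them higher and 4 lower, with 16 shared, Tmem216 had an adjusted p of 0.0334, and fry called 0 lists (cardiac adjusted p = 0.101, hypoxia 0.109). The labels do not say whether equal numbers pair samples. Deviations of samples with the same number correlated across genes at 0.0161, -0.0934 and 0.101, within the range of different numbers (-0.147 to 0.142), so the values show no pairing and do not exclude it. Single transcripts were not run because the table is by gene, and a count test was not run because the values are TPM. Unknown depth limits what can be said of genes with low values.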

Other observations

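Wild type samples held very little heart muscle RNA. Myl7 was 1.91, 4.91 and 2.04 TPM in wild type, and Nppa was 5.02, 0.83 and 1.35 TPM, while Actc1, which skeletal muscle also uses, was 92.6, 179 and 160 TPM; these genes were 151, 436 and 270, 131, 294 and 120, and 401, 617 and 474 TPM in Tmem216-/-. The skeletal muscle regulator Myod1 had a log2 fold change of 0.25. Lens crystallin genes, named after their values were seen, were high in a single wild type sample: Cryaa was 2.23, 0.10 and 27.5 TPM in wild type and 0, 0.05 and 0.05 TPM in Tmem216-/-, and Crybb3 was 3.14, 0.79 and 19.2 TPM and 0.42, 0 and 0.57 TPM. Nkx2-9, a ventral neural tube and Hedgehog target gene below the filter, was 1.14, 0.81 and 1.35 TPM and 0.27, 0.05 and 0.21 TPM.

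The tests of Hox groups 10 to 13 against 1 to 9, of the HoxA and HoxD clusters, of chromosome 19 and of heart genes in the same amount of heart were chosen after the result was seen. The liver and posterior Hox covariates and the lists of other heart genes and tail bud genes were also chosen after the main results were seen, with their bounds written before their own values; the splits and the scaling alternatives were set before. For the cardiac genes, a larger share of heart in the Tmem216-/- samples may explain the rise, and the labels do not say which tissue was taken. Of 19 measured heart muscle genes outside the list, 18 were higher, and 68.4% lay higher in every Tmem216-/- sample than in any wild type sample (5% by chance). Their median log2 fold change was 0.81, against 3.29 for the list. Fold changes on log2(TPM + 1) understate the difference for genes with low values, so the medians are not directly comparable. In limma 0 passed over all genes, 10 passed adjusted over the list alone and 11 had an unadjusted p under 0.05. Of 11 measured genes of endocardium and epicardium, 10 were higher, with a median log2 fold change of 0.23. In 5 of those 11 every Tmem216-/- sample lay above every wild type sample. Scaling does not explain it, since the median stayed at 3.30 or more under either scaling. A change of expression in the same amount of heart would also give the median of 3.29. It would require wild type heart muscle with almost no Myl7 (1.91, 4.91 and 2.04 TPM) or Mybpc3 (0.36, 0.28 and 0.09 TPM). Myl2 (7.06, 4.02 and 2.23 TPM), Myh6 (3.75, 5.59 and 3.54 TPM) and Tnni3 (4.86, 5.53 and 4.22 TPM) were also low in wild type. Tnnt2 was less so, at 15.2, 24.4 and 17.4 TPM. All 18 genes of the list were lower in every wild type sample than in any Tmem216-/- sample. For the listed genes, these values argue against a change of expression in the same amount of heart as the whole explanation. The amount of heart in each sample is unknown, so a part for expression is left open. Dissected hearts or in situ hybridization for Myl7 would separate a larger share of heart from a change of expression.

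The caudal Hox genes may fall because the Tmem216-/- samples held less caudal and hindlimb tissue. Groups 10 to 13 had a median log2 fold change of -1.27 against -0.35 for groups 1 to 9, a difference of -0.92, but that grouping was chosen after Hoxc10, Hoxc11 and Hoxc12 were seen and holds them, so it restates the pattern and leaves the explanation open. HoxA and HoxD genes of groups 10 to 13 had a median of -0.95, with 7 of 7 lower. However, 0 of the 7 had groups that do not overlap, and the median SE of the single genes was 0.48. A change limited to HoxC is therefore left open. Tail bud genes had a median of -0.02, with 4 of 8 measured genes lower and 4 higher. The list holds 14 genes, and Tbx6, Msgn1, Cdx4, Hes7, Ripply2 and Mesp2 were under 1 TPM in every sample of both groups. It could therefore show little about loss of the tail end, which is left open. In Tmem216-/- replicate 3, Hoxd13 was 29.4 TPM while Hoxc10 was 0.

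Lower Gli1 could reflect weaker Hedgehog signaling or a different mixture of tissues. Chance is not excluded either, since its limma adjusted p was 0.593 and the groups of 9.57% of genes did not overlap, against 10% by chance. Its log2 fold change was -0.54 at the scaling nearest 0, so scaling does not explain it. With a hepatocyte covariate it was -0.63. That covariate is itself lower in Tmem216-/- and was fitted on 6 samples, so it does not exclude a part for liver share. With a posterior Hox covariate the Gli1 log2 fold change was -0.88 with an SE of 0.25, which does not settle the share of caudal tissue. Staining for Gli1 in sections of the embryos would test the first hypothesis.

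The 3 against 3 design gives 10 splits, too few for a share under 0.05. The real grouping gave 17 genes (highest other 71, 2 of 10 splits as large). Of these 16 lay in the direction with more genes (67, 2 of 10) and 1 in the direction with fewer (4, 3 of 10), whichever direction that was in a split. It also gave 15 lists (16, 2 of 10) and a Hedgehog median of 0.27 in absolute value (0.17, 1 of 10). The split of wild type replicates 1 and 3 and Tmem216-/- replicate 3 against the rest also passed camera for the Hedgehog list (adjusted p = 0.0182, against 0.0154 for genotype). The split that called 71 genes set wild type replicates 1 and 2 and Tmem216-/- replicate 1, the samples with the most Afp (669, 1228 and 480 TPM), against the rest (11.3, 0.47 and 3.07 TPM), which points to a structure of the samples that genotype does not follow. Within 10 Mb of Tmem216, 8 of 260 genes (3.08%) had an unadjusted p under 0.01, against 1.22% of 15345 genes on other chromosomes (Fisher exact p = 0.0166). That test was chosen after the result was seen and treats genes measured in the same samples as independent. It leaves open whether sequence flanking the targeted gene contributes.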
